A study of Mus musculus with 10 samples.

How the data were processed

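Total RNA of 10 mouse samples was measured on one-colour Agilent oligonucleotide arrays with Cy3 label, 1 array per sample. Each of 5 groups had 2 arrays: the leukemias of mice 686, 713 and 760 (dHet-B-ALL), cultured dHet pro-B cells and sorted wt pro-B cells. The leukemias came from lymph nodes of Ebf1+/- Pax5+/- mice. The dHet pro-B cells were c-Kit-positive fetal liver cells of Ebf1+/- Pax5+/- Rag2-/- genotype, kept in short-term culture on OP9 feeder cells with IL-7, Flt3 ligand and stem cell factor. The wt pro-B cells were Fraction BC cells of control bone marrow. The labels do not say whether the 2 replicates of a group are separate animals, cultures or labellings.

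Per the file headers, each deposited scanner file holds intensity values made by Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 9.1. The authors' scanner software subtracted a spatially detrended background, removed a multiplicative trend and replaced the lowest values by surrogates, within each array and not between arrays. The mean spot brightness and the median local background in the same files are uncorrected intensity values, per the file headers. The files also mark each spot as well above background, saturated or an outlier. The deposited value table of the authors holds log2 values of 41267 probes, of which 41174 matched the scanner files. Its columns share a maximum of 18.5 and medians between 6.83 and 6.85, as quantile normalization leaves them. How its background, centring and floor were set is unknown. Per array it correlated with the log2 processed signal at r between 0.927 and 0.974 and with a normexp-corrected signal at r between 0.937 and 0.999.

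Each array had 45018 spots, 43379 of them non-control, for 41174 probes. Control spots and spots marked as outliers were left out, and the spots of a probe were averaged. Where all spots of a probe were outliers on an array, their average was kept, as for 211 probes on some array. No spot was saturated. The processed signal was log2 transformed and each array's 75th percentile was subtracted, so a level of 0 is that percentile. A probe was kept when it was well above background on all arrays of at least 1 of the 5 groups, which 22300 probes were. Probe names were taken from a table of mouse RefSeq genes (GRCm38.p6) by accession (28223 probes), symbol (5394) or synonym (349), and 7208 kept the name in the files. Coordinates are on mm9, per the file headers. Of 14455 genes, 11631 had a gene symbol and 5366 had several probes. A gene is represented by its brightest kept probe over the 10 arrays. Probes of immunoglobulin, T cell receptor and H2 genes share sequence between family members.

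Changes were tested with limma 3.58.1 in R 4.3.3, with tables handled by the R package data.table at version 1.17.8, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The leukemias were compared with each kind of pro-B cell over 7 samples (3 mice, 2 dHet and 2 wt arrays, 4 residual degrees of freedom). The 2 arrays of a leukemic mouse were averaged, so that the mouse was the replicate of a leukemia. The spread was pooled over the mouse means and the single pro-B arrays. These p-values therefore measure the spread between mice only in part. The dHet and wt pro-B cells, and each leukemia against the other 2, were compared over all 10 arrays in 5 groups with 5 residual degrees of freedom. In the comparisons of the pro-B groups and between leukemias the p-values measure the spread between the 2 arrays of a group, pooled over all 5 groups. The pool mixes leukemia and pro-B arrays, and the spread between leukemic mice is not measured. A change is the difference of group means on the log2 scale with its standard error (SE) from limma. Where no array of 1 group was well above background for a gene, the change is given as a bound. The bound is the other group's mean level against the dimmest level well above background on the arrays of the undetected group. For named genes detected on only part of the lower group's arrays, the change with the undetected arrays at that dimmest level is given where it altered the fold by more than 1.5 times. Where another probe of a named gene differed in its call, this is said beside the gene. A gene called by its main probe had another probe passing in the opposite direction in 398 of 3017 genes with several probes for the leukemias against wt. The same held for 150 of 2496 genes against dHet pro-B and 36 of 1458 between the pro-B groups.

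The comparisons, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where a choice is said to be added. Named were the 10 largest changes per direction for each comparison with pro-B cells, among genes with a symbol, past the threshold, bright in the higher group and changed alike in every mouse by at least 2-fold, or between pro-B groups without overlap of the arrays. For each leukemia the 5 largest per direction were named. The 2 highest and 2 lowest members of a list past the threshold and 23 fixed genes were also named. Some of these genes are withheld for evaluation and are not reported here. Restricting the largest changes to genes measured in both groups, and naming the 5 largest bounds per direction, were added after the data were seen.

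The 28 gene lists held 637 entries and were tested with limma's camera at a preset correlation of 0.01, on lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Lists of B cell development covered B cell genes activated by EBF1 and PAX5, genes described as repressed by PAX5, the pre-B cell receptor and V(D)J recombination, later B cell stages, plasma cells and MHC class II. Lists of signalling and growth covered IL-7 receptor components, STAT5 targets, MYC targets with ribosome biogenesis, the cell cycle and DNA replication, p53 targets, the BCL2 family, interferon-stimulated genes, hypoxia, and immediate early and handling stress genes. Lists of metabolism covered folate and one-carbon metabolism, serine, purine and pyrimidine synthesis, glycolysis and cholesterol synthesis. Lists of leukemia and progenitors covered genes altered in B-ALL, stem and progenitor genes and fetal-type genes. Lists of other cells covered T cells, NK and cytotoxic cells, myeloid cells, erythroid cells and megakaryocytes, stromal cells, and endothelium with lymph node stroma. The IL-7, MYC and folate lists were chosen knowing what the study is about, so their direction is not independent evidence.

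The 75th percentile of the processed signal lay between 137 and 520 intensity units per array, and between 35.7% and 52.4% of probes were well above background. With 2 arrays per group, the number of arrays limits the precision. In simulated data with 50 changed genes per size, 0% of 2-fold and 28% of 4-fold changes of all 3 leukemias against wt were recovered, with 6 false calls among 14255 unchanged genes. Recovery was 4% and 46% against dHet pro-B, 6% and 70% between the pro-B groups, and 26% and 66% for leukemia 713 against the other 2. The simulations left 14255 of 14455 genes unchanged, whereas 58.7%, 46.2%, 31.6% and 15.3% of genes passed in these comparisons of the data. The adjustment is stricter when few genes change, so the recovered shares do not give the power of the reported comparisons.

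The replicate 1 arrays of the leukemias shared slide 1, their replicate 2 arrays slide 2, and the 4 pro-B arrays slide 3. Slides 2 and 3 were scanned on 1 day and slide 1 on another. Replicate differences were correlated between leukemias (r of 0.54, 0.44 and 0.63 across genes) and not with or between the pro-B groups (r between -0.03 and 0.08). The replicate numbers thus pair the leukemia arrays. Slide and scan day changed together between them and cannot be told apart as the source. Alternatives were run one by one against the main choice. Of these, 2 changed several choices of the signal together: the mean spot signal with normexp background correction (offset 50) in place of the processed signal, and the authors' value table. The others were quantile normalization, scaling by the array median, no filter or a filter on all 10 arrays, the mean of a gene's probes, a variance trend, a 2-fold minimum, slide, scan day, mouse or replicate as a block, arrays as replicates, fewer groups in the fit, and leaving out each array or mouse. For the leukemias against pro-B cells, the fits with slide, scan day or replicate as a block also took arrays as replicates in place of mice. Their counts there do not show the effect of the block alone. Added after the data were seen were a 75th percentile over probes detected on all 10 arrays, leukemia arrays of slide 1 or slide 2 only, slide as a random block for the lists, leaving out sex-linked genes, and separate wt arrays for the overlap. Other splits of the samples were not counted, since no comparison had at least 3 samples in each group.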

Results

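Gene expression was measured on 10 arrays, 2 for each of 5 groups. The B cell acute lymphoblastic leukemias (B-ALL) of 3 mice, 686, 713 and 760, came from animals with 1 intact copy each of Ebf1 and Pax5 (dHet), the genes of transcription factors that establish and keep B cell identity. The dHet pro-B group was fetal liver pro-B cells of the same double heterozygous genotype, also Rag2-deficient. They were cultured on OP9 feeder cells with IL-7, Flt3 ligand and stem cell factor. The wt pro-B group was freshly sorted from bone marrow of control mice. Replicates correlated across genes at r of 0.953, 0.973 and 0.975 in leukemias 686, 713 and 760, 0.992 in dHet pro-B and 0.994 in wt pro-B. Leukemia arrays of different mice correlated at r between 0.921 and 0.964, leukemia with dHet pro-B arrays between 0.876 and 0.904, and leukemia with wt pro-B arrays between 0.837 and 0.870. Replicate 1 of leukemia 686 had the lowest share of probes well above background, 35.7%, against 42.1% to 52.4% on the other arrays. In 1 of the 5 groups the 2 arrays did not match each other in sex-linked genes, so they were not from the same RNA. Leukemia and pro-B arrays shared no slide, so slide and group cannot be told apart between them.

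The first comparison asked how the 3 leukemias differed from normal pro-B cells. They also differed in tissue (lymph node against bone marrow) and in Ebf1 and Pax5 genotype, which cannot be told apart from leukemia. Myc, which encodes a transcription factor of cell growth, was 10.6-fold higher in the leukemias than in wt pro-B cells (log2 change 3.40 ± 0.34 SE, n = 3 mice against 2 wt arrays, adjusted p = 0.000779). Shmt2, the mitochondrial enzyme that passes one-carbon units from serine to folate, was 9.07-fold higher (3.18 ± 0.18, adjusted p = 0.000246). Cish, a feedback inhibitor of cytokine signalling induced by STAT5, was 11-fold higher (3.45 ± 0.25, adjusted p = 0.000361). Ikzf1, which encodes the lymphoid transcription factor IKAROS, was 9.69-fold lower (-3.28 ± 0.12, adjusted p = 0.000158). Each of these genes moved the same way in all 3 mice, as did every other gene named here as changed. In all, 4516 genes were higher and 3974 lower among 14455, 2680 and 2970 of them by at least 2-fold.

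Pax5 was lower (-4.05 ± 0.79, adjusted p = 0.00692), but its probe was well above background on only 2 of the 6 leukemia arrays, both of leukemia 713. With the undetected arrays at the lowest level well above background it was 7.83-fold lower. Ebf1 fell by 1.05 ± 0.14 on the log2 scale (adjusted p = 0.00174) at its brightest probe, on chromosome 11 from 44818365 to 44818424. Its second probe, from 44462618 to 44462677, fell by 4.14 ± 0.22. The recombinase genes Rag1 (-1.83 ± 0.22) and Rag2 (-1.15 ± 0.16) were lower. The surrogate light chain gene Vpreb1 rose by 0.91 ± 0.16, and Kit, the stem cell factor receptor, by 1.95 ± 0.56. Flt3, the Flt3 ligand receptor, rose by 2.43 ± 0.81 and Mthfd2, of mitochondrial folate metabolism, by 1.17 ± 0.22. Socs2, another STAT5-induced feedback inhibitor, rose by 3.59 ± 0.14, but its second probe did not pass (0.34 ± 0.39). The surrogate light chain gene Igll1 rose by 1.47 ± 0.24 and the thymidylate synthase gene Tyms by 1.96 ± 0.22, and another probe of each did not pass. Dntt (adjusted p = 0.399), Il7r (0.982), Bcl2 (0.442), Mycn (0.0729), Cdkn2a (0.332) and Lin28b (0.407) did not pass. Other probes of Il7r (-1.11 ± 0.30) and Bcl2 (-1.30 ± 0.45) were lower.

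The largest increase was that of Ffar2, a receptor for short-chain fatty acids, at 181-fold (7.50 ± 0.42). Dipk1b (7.13 ± 0.64), Tmem40 (6.96 ± 0.76), Tmem119 (6.91 ± 0.49), Myl10 (6.78 ± 0.35) and the calcium-binding protein gene S100a4 (6.27 ± 1.21) followed, and Ifitm1, Tmem121, Prnp and Evpl rose by between 5.28 and 5.68. The largest decreases included Fcrla, an Fc receptor-like gene of B cells (-7.40 ± 1.86), Polm, a DNA polymerase (-7.26 ± 1.72), and Lgr5, a receptor that enhances WNT signalling (-6.73 ± 1.11). Lgr5 was well above background on 2 of 6 leukemia arrays, and its change was -5.43 with the others at the lowest level well above background. The largest decreases also included the IgM receptor gene Fcmr (-6.44 ± 0.64), Ms4a1, which encodes CD20 (-6.15 ± 0.66), and Cd83 (-5.99 ± 0.21). Among genes measured on 1 side only, Farp1 was at least 56.6-fold and Crisp1 at least 53.2-fold higher, and Col5a3 was at least 231-fold and Fos at least 61.4-fold lower.

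**Figure D1:**
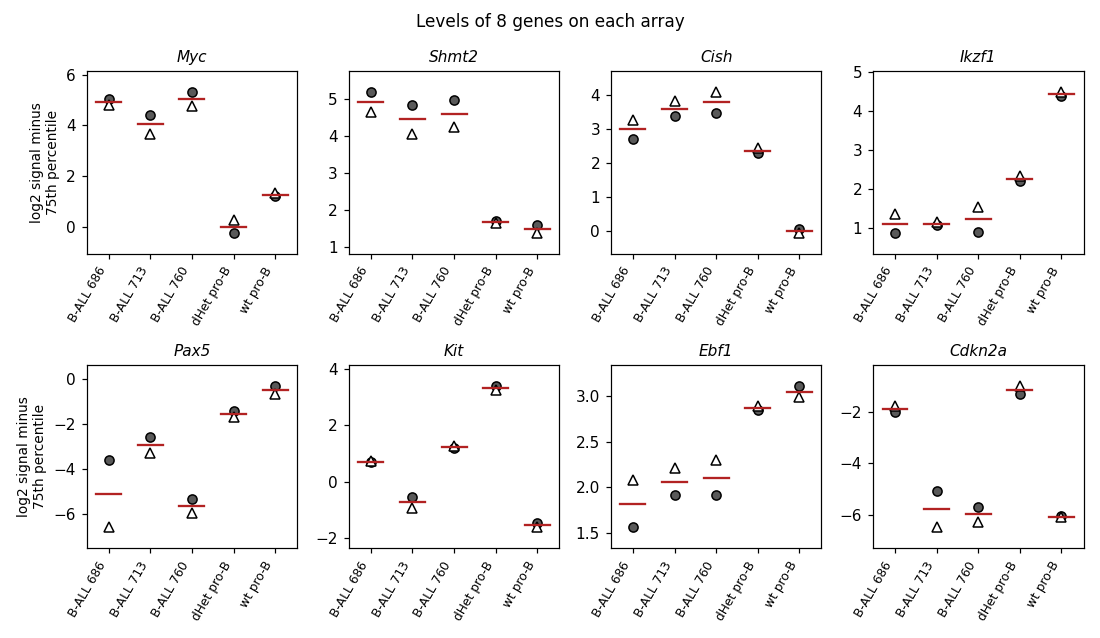
Level of 8 named genes on each array (log2 signal relative to the array's 75th percentile), with replicate 1 as filled circles, replicate 2 as open triangles and a red line at each group's mean. Myc lies between 3.68 and 5.32 on the 6 leukemia arrays and between -0.24 and 1.33 on the 4 pro-B arrays, and Ikzf1 between 0.88 and 1.55 against 2.22 to 4.49.

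Growth and metabolism genes rose together. Of the MYC targets and ribosome biogenesis genes, 44 of 45 rose (45 adjusted over the list alone), led by the spermidine synthase gene Srm (3.36 ± 0.23) and the nucleolar gene Gnl3 (3.21 ± 0.19). The median change of the list was 1.86 (camera adjusted p = 5.21e-14; adjusted p = 0.634 with an estimated correlation), and the list was chosen knowing the study's topic, so it is not independent evidence. Of 24 folate and one-carbon genes, chosen in the same way, 15 rose and 2 fell (16 and 2 adjusted over the list alone). The folate carrier gene Slc19a1 rose by 3.78 ± 0.16 and Shmt1 by 3.24 ± 0.28, while the folate transporter gene Slc46a1 fell by 2.01 ± 0.22 and Aldh1l1 was at least 2.33-fold lower. The median of the folate list was 1.06 (adjusted p = 0.000564; adjusted p = 0.634 with an estimated correlation). In serine, purine and pyrimidine synthesis 27 of 29 genes rose (28 adjusted over the list alone), among them Atic (3.14 ± 0.18), with a median of 1.81 (adjusted p = 1.13e-08; adjusted p = 0.634 with an estimated correlation). Of 40 cell cycle and DNA replication genes 36 rose (37 adjusted over the list alone), such as Cdk1 (2.82 ± 0.22) and Kif20a (2.47 ± 0.15), with a median of 1.29 (adjusted p = 4.53e-09; adjusted p = 0.634 with an estimated correlation). Of 20 glycolysis genes 15 rose (15 adjusted over the list alone), such as Pdk1 (3.33 ± 0.14) and Hk2 (2.97 ± 0.23), with a median of 2.0 (adjusted p = 9.33e-06; adjusted p = 0.634 with an estimated correlation). In cholesterol synthesis 11 of 20 genes rose and 1 fell (11 and 1 adjusted over the list alone), with Sqle at 3.40 ± 0.42 and the feedback regulator Insig1 at -1.99 ± 0.50, and a median of 1.05 (adjusted p = 0.0203; adjusted p = 0.809 with an estimated correlation).

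B cell genes fell more often than they rose. Of 35 B cell genes activated by EBF1 and PAX5, 21 fell and 3 rose (22 and 3 adjusted over the list alone), with a median of -1.07 (adjusted p = 0.00106; adjusted p = 0.809 with an estimated correlation). Fcrla and Cd72, an inhibitory co-receptor (-5.57 ± 0.66), had the lowest values. Of 25 genes of later B cell stages 10 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.58 (adjusted p = 0.0352; adjusted p = 0.809 with an estimated correlation). Immediate early and handling stress genes, which respond within minutes to stimulation and cell isolation, fell in 23 of 24 cases (23 adjusted over the list alone), with Fosb at least 32.7-fold lower. Their median was -3.25 (adjusted p = 4.53e-09; adjusted p = 0.0633 with an estimated correlation). Markers of other cells moved as well, and whether leukemia cells or other cells of the samples held these transcripts was not tested. Of 16 T cell markers 9 rose (8 adjusted over the list alone), such as Cd3d (4.37 ± 0.47), with a median of 2.12, or 1.78 with genes measured on 1 side at their bounds (adjusted p = 0.0174; adjusted p = 0.553 with an estimated correlation). Of 9 NK and cytotoxic markers 4 rose (4 adjusted over the list alone), such as Nkg7 (4.10 ± 1.11) and Ccl5 (3.84 ± 0.82), but the list did not pass (adjusted p = 0.0837). Of 22 myeloid markers 7 fell and 2 rose, 2 of the falls holding when adjusted over the list alone, with Camp (-5.63 ± 1.37) and S100a9 (-5.18 ± 1.71) among the genes that fell, and the list did not pass (adjusted p = 0.0862). Camp was well above background on 1 of 6 leukemia arrays, and was 17.9-fold lower with the others at the lowest level well above background.

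The other lists did not pass in this comparison. Of 16 genes described as repressed by PAX5, 7 rose and 3 fell (9 and 4 adjusted over the list alone), with the adhesion gene Emb up by 4.25 ± 0.18 and Cd7 at -4.07 ± 0.28 (list adjusted p = 0.484). Of 19 genes of the pre-B cell receptor and V(D)J recombination, 4 rose and 6 fell (4 and 6 adjusted over the list alone), with the DNA end-binding gene Xrcc5 at 2.86 ± 0.43, Ighm at -2.80 ± 0.29 and the DNA ligase gene Lig4 at -2.79 ± 0.29 (adjusted p = 0.484). Of 11 plasma cell genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; list adjusted p = 0.494), with Irf4 at -3.54 ± 0.33 and Mzb1 at 1.53 ± 0.14. Of 10 MHC class II genes, Ciita, their master regulator (-2.43 ± 0.69), and H2-Ob (-2.04 ± 0.66) fell and 8 did not pass, and neither fall held adjusted over the list alone (list adjusted p = 0.0837). Of 13 IL-7 receptor components, a list chosen knowing the topic, 3 rose and 1 fell, and 2 rises held adjusted over the list alone (list adjusted p = 0.890); Stat5a rose by 1.22 ± 0.15. Of 16 STAT5 targets 6 rose and 4 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.858), with a median of -0.05 but a mean of 0.71; the survival gene Bcl2l1 fell by 2.42 ± 0.34. Of 14 BCL2 family genes 6 rose and 4 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.858), with Bok at 4.29 ± 0.41 and the death-promoting Bmf at -2.75 ± 0.67. Of 34 genes altered in B-ALL 9 rose and 13 fell (9 and 14 adjusted over the list alone; list adjusted p = 0.375), with the transcription factor gene Tal1 at 3.95 ± 0.32 and Hoxa7 at -4.55 ± 0.24. Of 19 p53 targets 4 rose and 7 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.372), with Btg2 at -3.82 ± 0.41.

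Of 15 stem and progenitor genes 5 rose and 4 fell (5 and 5 adjusted over the list alone; list adjusted p = 0.890). Of 9 fetal-type genes 2 rose and 1 fell, and 2 rises held adjusted over the list alone (list adjusted p = 0.375), with the RNA-binding protein genes Igf2bp2 at 3.02 ± 0.24 and Igf2bp3 at 2.98 ± 0.24. Of 15 hypoxia genes 8 rose and 3 fell (8 and 3 adjusted over the list alone; list adjusted p = 0.346), with Bhlhe40, detected on 1 of 6 leukemia arrays, at -4.31 ± 0.49, or -3.59 with the others at the lowest level well above background. Of 25 interferon-stimulated genes 3 rose and 4 fell (2 and 4 adjusted over the list alone; list adjusted p = 0.648). Of 10 erythroid and megakaryocyte markers 2 rose and 3 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.97), with a median of 0.27 and a mean of 0.71 against a list test in the downward direction. Of 15 stromal markers 1 rose and 5 fell, 2 of the falls holding adjusted over the list alone (list adjusted p = 0.484), with Vcam1 at -2.63 ± 0.70. Of 8 endothelial and lymph node stroma markers 3 rose and 2 fell (3 and 2 adjusted over the list alone; list adjusted p = 0.915), with Egfl7 at 3.46 ± 0.56.

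**Figure D2:**
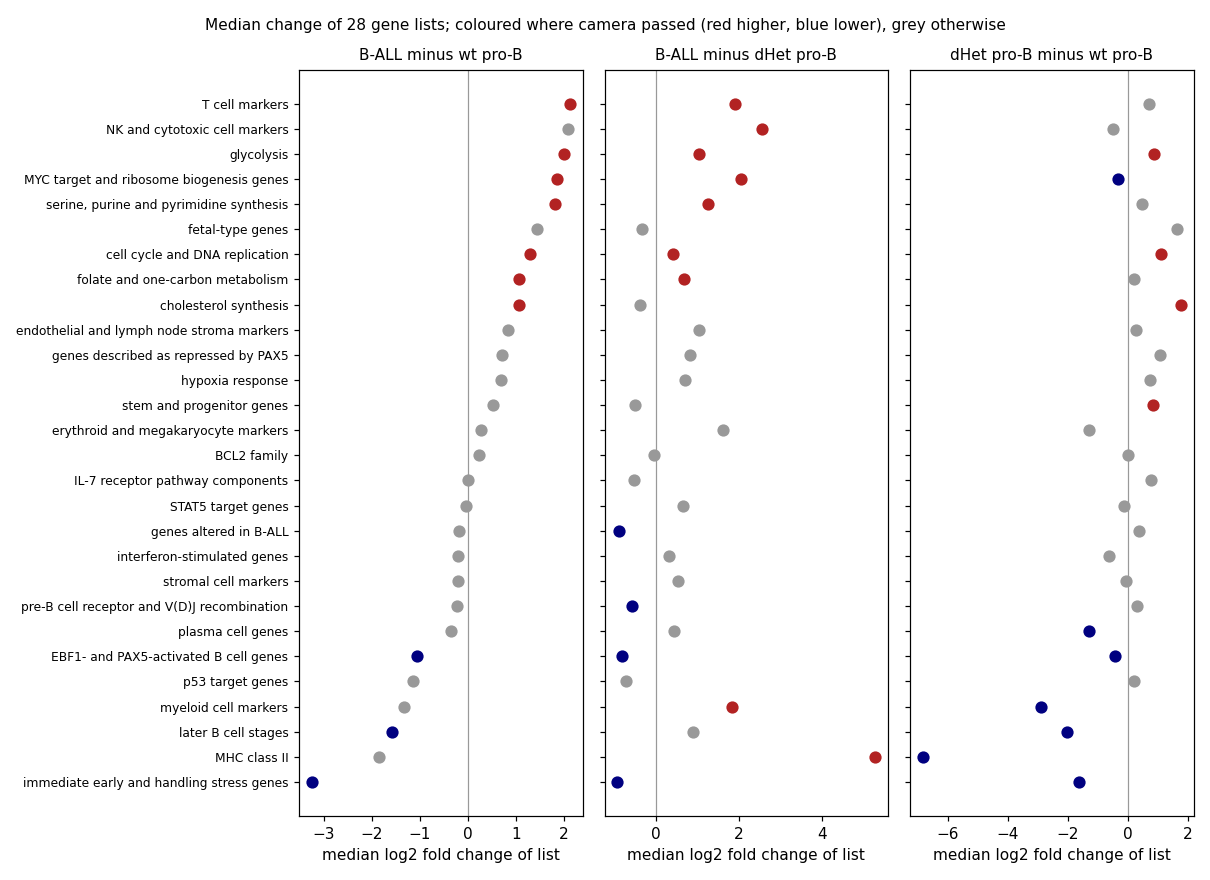
Median log2 change of each of the 28 gene lists in the 3 comparisons with pro-B cells, in red for lists that rose and in blue for lists that fell by camera at a preset correlation of 0.01. The MYC list has medians of 1.86 and 2.04 in the leukemias against wt and dHet pro-B cells and -0.32 in dHet against wt pro-B cells, where scaling by the array median gives 0.03; no list passes with an estimated correlation.

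The direction of the list median depended on the scaling for the pre-B cell receptor, plasma cell, IL-7, STAT5, BCL2 family, B-ALL, interferon, erythroid and stromal lists, none of which passed. The median change of all genes was 0.06, and 0.63 with scaling by the array median, where 6366 genes were higher and 2280 lower. It was -0.30 with scaling on probes detected on all arrays, where 2959 were higher and 5483 lower. Slide and group cannot be told apart here. With slide as a random block 2978 genes were higher and 2192 lower, and with scan day as a block 5251 and 4929. Both fits also took arrays as replicates in place of mice. With camera run on the slide 2 leukemia arrays only, 7 lists rose and 3 fell, as with both slides, and with slide as a random block 8 rose and 4 fell.

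The second comparison asked how the leukemias differed from dHet pro-B cells of the same Ebf1 and Pax5 genotype that were not leukemic. The groups also differed in tissue (lymph node against c-Kit-positive fetal liver cells), culture and Rag2 genotype, which cannot be told apart from leukemia. Myc was 25.4-fold higher in the leukemias (4.67 ± 0.34, n = 3 mice against 2 dHet arrays, adjusted p = 0.000743) and Shmt2 7.94-fold higher (2.99 ± 0.18, adjusted p = 0.000484). Kit was 7.53-fold lower (-2.91 ± 0.56, adjusted p = 0.00941) and Pax5 lower (-3.00 ± 0.79, adjusted p = 0.0259), or 3.78-fold lower with the undetected arrays at the lowest level well above background. The MHC class II gene H2-Ab1 was 76.7-fold higher (6.26 ± 0.62, adjusted p = 0.00134). In all, 3140 genes were higher and 3532 lower, 1870 and 2129 of them by at least 2-fold, and each gene named as changed moved the same way in all 3 mice. Rag1 (-2.13 ± 0.22), Rag2 (-1.80 ± 0.16), Il7r (-1.01 ± 0.25), Ebf1 (-0.87 ± 0.14), Ikzf1 (-1.12 ± 0.12) and Vpreb1 (-0.56 ± 0.16) were lower, Vpreb1 turning to 0.07 with quantile normalization. Lin28b, an RNA-binding regulator of fetal blood formation, was at least 2.0-fold lower. Cish (1.1 ± 0.25) and Mthfd2 (1.44 ± 0.22) were higher. Socs2 (0.54 ± 0.14) and Tyms (0.93 ± 0.22) were higher at the main probe, and another probe of each did not pass (-0.98 ± 0.39 and 0.84 ± 0.40). Dntt (adjusted p = 0.911), Igll1 (0.303), Bcl2 (0.156), Mycn (0.412), Cdkn2a (0.0705) and Flt3 (0.103) did not pass at the main probe. Another probe of Bcl2 rose by 1.07 ± 0.32, and a second Igll1 probe fell by 1.69 ± 0.27.

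The largest increases included the immunoglobulin light chain segment Iglv1 (7.81 ± 1.01), Jchain, which joins secreted immunoglobulin polymers (7.27 ± 0.88), the chemokine gene Ccl5 (6.29 ± 0.82) and Cd74, the MHC class II chaperone (6.29 ± 1.16). Mylk (6.09 ± 0.28), Ighg3 (5.84 ± 0.98), Dipk1b (5.78 ± 0.64) and Gimap3 (5.65 ± 0.38) were also among them. Whether the increases of this comparison came from leukemia cells or from other cells in the lymph node samples was not tested. Csf1r, the receptor for a macrophage growth factor, was higher at the main probe, which was well above background on no dHet pro-B array, with a change of 3.40 when those arrays were set at the lowest level well above background. Its second probe did not pass (1.56 ± 0.75). Ly86 was at least 821-fold, the alpha globin genes Hba-a1 and Hba-a2 at least 236-fold and 185-fold, and the cyclin gene Ccnd1 at least 83.0-fold higher. The largest decreases included the chemokine gene Ccl9 (-8.35 ± 0.38), Slco1b2 (-7.39 ± 0.35), Bmpr2 (-7.31 ± 0.43), Kynu (-6.31 ± 0.50) and the asparagine synthetase gene Asns (-5.90 ± 0.60). Slco1b2 and Bmpr2 were well above background on 1 of 6 leukemia arrays and Asns on 2, and with the others at the lowest level well above background their changes were -6.39, -5.97 and -5.21. The growth factor gene Igf2 was at least 35.2-fold lower. Whether RNA of the OP9 feeder cells in the dHet culture added to the decreases of this comparison was not tested.

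MYC targets and ribosome biogenesis genes rose in 42 of 45 cases (43 adjusted over the list alone), with Srm at 4.75 ± 0.23. The MYC list had a median of 2.04 (adjusted p = 3.77e-20; adjusted p = 0.472 with an estimated correlation). Of 24 folate genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Slc19a1 at 2.89 ± 0.16. The folate list had a median of 0.69 (adjusted p = 0.00193; adjusted p = 0.472 with an estimated correlation). Both lists were chosen knowing the topic and are not independent evidence. Serine, purine and pyrimidine synthesis had 23 of 29 genes higher and 1 lower (26 and 1 adjusted over the list alone), with the serine pathway gene Phgdh at 2.87 ± 0.16. This synthesis list had a median of 1.26 (adjusted p = 3.9e-08; adjusted p = 0.472 with an estimated correlation). Glycolysis had 12 of 20 genes higher (12 adjusted over the list alone), with Hk2 at 3.22 ± 0.23. The glycolysis list had a median of 1.04 (adjusted p = 0.000558; adjusted p = 0.472 with an estimated correlation). Cell cycle genes rose in 10 and fell in 2 of 40 cases (7 and 2 adjusted over the list alone), with Mcm2 at 1.19 ± 0.14. The cell cycle list had a median of 0.41 (adjusted p = 0.0307; adjusted p = 0.687 with an estimated correlation).

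MHC class II genes rose in 8 of 10 cases (8 adjusted over the list alone), with H2-Aa at least 47.3-fold and H2-Eb1 at least 35.0-fold higher. The class II list had a median of 5.26, or 4.35 with bounds (adjusted p = 0.0111; adjusted p = 0.676 with an estimated correlation). Of the B cell genes activated by EBF1 and PAX5, 16 of 35 fell and 4 rose (16 and 4 adjusted over the list alone), with Cd72 at -3.15 ± 0.66 and the cytokine receptor gene Tnfrsf13c at 2.84 ± 0.49. The activated genes had a median of -0.81 (adjusted p = 0.0388; adjusted p = 0.687 with an estimated correlation). Of 19 genes of the pre-B cell receptor and V(D)J recombination 10 fell and 1 rose (10 and 1 adjusted over the list alone), with Lig4 at -2.72 ± 0.29 and Ighm at -2.39 ± 0.29. The recombination list had a median of -0.56 (adjusted p = 0.0188; adjusted p = 0.472 with an estimated correlation). Of 34 genes altered in B-ALL 15 fell and 2 rose (16 and 2 adjusted over the list alone), with Hoxa7 at -3.77 ± 0.24. These genes together had a median of -0.87 (adjusted p = 0.024; adjusted p = 0.472 with an estimated correlation). Immediate early and handling stress genes fell in 12 of 24 cases and rose in 1 (12 and 1 adjusted over the list alone), with Hspa1a, detected on 2 of 6 leukemia arrays, at -3.11 ± 0.47, or -2.41 with the others at the lowest level well above background. The stress list had a median of -0.91, or -0.47 with bounds (adjusted p = 0.024; adjusted p = 0.472 with an estimated correlation). Markers of other cells rose beside them, and whether leukemia cells or other cells of the lymph node samples held these transcripts was not tested. T cell markers rose in 6 and fell in 1 of 16 cases (6 and 1 adjusted over the list alone), with Cd8b1 at least 30.8-fold higher. The T cell list had a median of 1.91, or 1.54 with bounds (adjusted p = 0.0379; adjusted p = 0.472 with an estimated correlation). NK and cytotoxic markers rose in 4 of 9 cases (4 adjusted over the list alone), with Ccl5 highest. The cytotoxic list had a median of 2.56, or 1.51 with bounds (adjusted p = 0.032; adjusted p = 0.588 with an estimated correlation). Myeloid markers rose in 7 and fell in 2 of 22 cases (7 and 1 adjusted over the list alone), with the complement gene C1qc at least 4.11-fold higher. The myeloid list had a median of 1.83, or 0.95 with bounds (adjusted p = 0.0307; adjusted p = 0.687 with an estimated correlation).

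Lists that did not pass here still held changed genes. Later B cell genes had 6 of 25 higher and 2 lower (6 and 2 adjusted over the list alone; list adjusted p = 0.0817), with Ms4a1 at least 19.7-fold higher. IL-7 receptor components, not independent evidence either, had 1 of 13 higher and 5 lower (1 and 5 adjusted over the list alone; list adjusted p = 0.169), with Il2rg at 1.42 ± 0.15 and Crlf2 at -1.33 ± 0.20. STAT5 targets had 4 of 16 higher and 2 lower (7 and 4 adjusted over the list alone; list adjusted p = 0.452), with the cyclin gene Ccnd2 at 2.92 ± 0.54 and Bcl2l1 at -2.24 ± 0.34. Of 14 BCL2 family genes 4 rose and 6 fell (4 and 6 adjusted over the list alone; list adjusted p = 0.947), with a median of -0.04 and a mean of 0.15. The other lists that did not pass were genes described as repressed by PAX5 (adjusted p = 0.472), plasma cells (0.431), cholesterol synthesis (0.169), hypoxia (0.180), p53 targets (0.183), stem and progenitor genes (0.0891), fetal-type genes (0.415), interferon-stimulated genes (0.309), erythroid cells (0.225), stroma (0.947) and endothelium (0.798).

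With slide as a random block 1872 genes were higher and 1437 lower, and with scan day as a block 4007 and 4819. Here too both fits took arrays as replicates in place of mice. The median change of all genes was -0.06, and 0.16 with scaling by the array median, where 3295 genes were higher and 1976 lower, or -0.20 on probes detected on all arrays, where 2645 were higher and 4302 lower. On slide 2 leukemia arrays 9 lists rose and 4 fell, as on both slides, and with slide as a random block 10 rose and 7 fell.

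The third comparison asked how dHet pro-B cells differed from wt pro-B cells before leukemia. The groups also differed in source, culture and Rag2 genotype, which cannot be told apart from the Ebf1 and Pax5 genotype. Kit was 29.0-fold higher in dHet pro-B cells (4.86 ± 0.18, n = 2 arrays against 2, adjusted p = 1.23e-05) and Cish 5.13-fold higher (2.36 ± 0.29, adjusted p = 0.00121). The dHet pro-B cells were obtained as c-Kit-positive cells, so their higher Kit may follow from that choice. Myc was 2.40-fold lower (-1.26 ± 0.32, adjusted p = 0.0223) and Ikzf1 4.47-fold lower (-2.16 ± 0.26, adjusted p = 0.00107). In all, 2415 genes were higher and 2148 lower, 1563 and 1825 of them by at least 2-fold, and both arrays of 1 group lay outside the range of the other for each gene named as changed. Cdkn2a, which encodes the p16 and p19 inhibitors of cell growth, was at least 7.68-fold higher. Vpreb1 (1.47 ± 0.21), Mycn (1.13 ± 0.23), Socs2 (3.05 ± 0.24) and Igll1 (1.80 ± 0.19) were higher. Il7r (1.01 ± 0.23) and Tyms (1.03 ± 0.24) were higher at 2 of 3 probes, the third not passing. Rag2 was higher (0.66 ± 0.17, adjusted p = 0.0249) although the cells were labelled Rag2-deficient; whether its probe on chromosome 2 lies in the deleted part is unknown. Ebf1 did not pass at its main probe (-0.18 ± 0.24, adjusted p = 0.606), while its second probe fell by 3.39 ± 0.25 (adjusted p = 0.000187). Pax5 (-1.05 ± 0.85, adjusted p = 0.397), Bcl2 (0.347), Mthfd2 (0.570), Shmt2 (0.728) and Flt3 (0.550) did not pass. The Pax5 levels did not overlap, at -1.40 and -1.67 on the dHet and -0.30 and -0.67 on the wt arrays. Its SE pools all 5 groups, including leukemia 686, where Pax5 was undetected at -3.59 and -6.57. The test therefore leaves open whether Pax5 was lower in dHet pro-B cells. Dntt (0.0802) and Rag1 (0.311) did not pass at the main probe, and another probe of each did (-0.88 ± 0.25 and 0.65 ± 0.20). Lin28b (0.129) did not pass at the main probe, and its other probe, which passed, was undetected in wt pro-B cells; another Bcl2 probe fell by 2.06 ± 0.44.

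The largest increases included Ccl9 (8.81 ± 0.45), Ifitm1 (6.27 ± 0.66), Septin8 (5.72 ± 0.18), the immunoglobulin Fc receptor gene Fcgr3 (5.45 ± 0.69), the metallothionein gene Mt1 (5.09 ± 0.41) and Ffar2 (5.08 ± 0.20). Slco1b2 was at least 106-fold and the placental growth factor gene Pgf at least 64.0-fold higher. Whether RNA of the OP9 feeder cells added to the increases of this comparison was not tested. Of 15 stromal markers 2 rose and 3 fell. The largest decreases included Iglv1 (-11.22 ± 0.46), Spns3 (-8.93 ± 0.40), Cd74 (-8.62 ± 0.75), H2-Ab1 (-7.80 ± 0.30) and the neutrophil protein genes S100a9 (-8.29 ± 0.91) and S100a8 (-7.66 ± 0.76). Ms4a1 was at least 1392-fold, Fcmr at least 861-fold, Ctsh at least 481-fold and Ly86 at least 474-fold lower.

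Cholesterol synthesis genes rose in 18 of 20 cases (19 adjusted over the list alone), with Sqle at 3.0 ± 0.40. The cholesterol list had a median of 1.77 (adjusted p = 7.28e-10; adjusted p = 0.0754 with an estimated correlation). Cell cycle genes rose in 24 of 40 cases (27 adjusted over the list alone), with Ube2c at 2.27 ± 0.36. The cell cycle list had a median of 1.1 (adjusted p = 7.24e-08; adjusted p = 0.397 with an estimated correlation). Stem and progenitor genes rose in 8 and fell in 1 of 15 cases (9 and 1 adjusted over the list alone), with Kit and the transcription factor gene Erg (2.30 ± 0.17) highest. The Kit value may follow from the c-Kit-positive source of the dHet pro-B cells. The progenitor list had a median of 0.85 (adjusted p = 0.0153; adjusted p = 0.256 with an estimated correlation). Glycolysis genes rose in 8 and fell in 2 of 20 cases (10 and 2 adjusted over the list alone), with Pdk1 at 2.38 ± 0.19. The glycolysis list had a median of 0.88 (adjusted p = 0.0407; adjusted p = 0.654 with an estimated correlation). The MYC list had 5 of 45 genes higher and 13 lower (5 and 13 adjusted over the list alone), with Npm1 at 1.57 ± 0.29, Srm at -1.39 ± 0.28 and a median of -0.32, which turned to 0.03 with scaling by the array median (adjusted p = 0.01; adjusted p = 0.654 with an estimated correlation). It was chosen knowing the topic and is not independent evidence.

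MHC class II genes fell in 8 of 10 cases (8 adjusted over the list alone), with H2-Aa at least 301-fold lower. The class II list had a median of -6.83, or -6.15 with bounds (adjusted p = 1.65e-09; adjusted p = 0.256 with an estimated correlation). Later B cell genes fell in 18 and rose in 1 of 25 cases (18 and 1 adjusted over the list alone), with a median of -2.01, or -1.92 with bounds (adjusted p = 2.59e-10; adjusted p = 0.278 with an estimated correlation). Plasma cell genes fell in 6 of 11 cases (6 lower and 1 higher adjusted over the list alone), with Jchain at -4.77 ± 0.54. The plasma cell list had a median of -1.30 (adjusted p = 0.00252; adjusted p = 0.59 with an estimated correlation). Of the B cell genes activated by EBF1 and PAX5, 16 of 35 fell and 8 rose (18 and 8 adjusted over the list alone), with Fcrla at -3.85 ± 0.83, Ciita at least 86.6-fold lower and Igll1 among the genes that rose. The activated genes had a median of -0.42 (adjusted p = 0.01; adjusted p = 0.643 with an estimated correlation). Immediate early and handling stress genes fell in 18 of 24 cases (19 adjusted over the list alone), with Fosb, detected on 1 of 2 dHet pro-B arrays, at -6.09 ± 1.23, or -5.00 with the other at the lowest level well above background. The stress list had a median of -1.64 (adjusted p = 7.7e-11; adjusted p = 0.0754 with an estimated correlation). Myeloid markers fell in 17 and rose in 2 of 22 cases (17 and 2 adjusted over the list alone), with S100a9 and S100a8 lowest. The myeloid list had a median of -2.88, or -2.66 with bounds (adjusted p = 6.64e-08; adjusted p = 0.371 with an estimated correlation).

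Of 13 IL-7 receptor components, not independent evidence, 6 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.107), with the kinase gene Jak3 at 2.06 ± 0.33. Of 9 fetal-type genes 4 rose and 1 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.110), with Igf2 at least 42.2-fold and H19 at least 11.1-fold higher. Interferon-stimulated genes had 3 of 25 higher and 8 lower (4 and 10 adjusted over the list alone; list adjusted p = 0.0915), with Oasl1 at -4.62 ± 0.46. Folate genes, also not independent evidence, had 6 of 24 higher (5 adjusted over the list alone; list adjusted p = 0.253). T cell markers had 4 of 16 higher and 3 lower (5 and 3 adjusted over the list alone; list adjusted p = 0.498), with Thy1 at 2.06 ± 0.32 and Cd8b1 at least 7.82-fold lower. Endothelial markers had 2 of 8 higher (2 adjusted over the list alone; list adjusted p = 0.334), with the VEGF receptor gene Kdr at 3.30 ± 0.38. The other lists that did not pass were genes described as repressed by PAX5 (adjusted p = 0.35), the pre-B cell receptor (0.218), STAT5 targets (0.909), serine, purine and pyrimidine synthesis (0.218), hypoxia (0.446), p53 targets (0.929), the BCL2 family (0.929), genes altered in B-ALL (0.35), NK cells (0.35), erythroid cells (0.152) and stroma (0.774). Median and mean differed in sign for STAT5 targets (-0.12 and 0.06), hypoxia (0.76 and -0.06), p53 targets (0.20 and -0.06) and the BCL2 family (0.01 and -0.13).

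**Figure D3:**
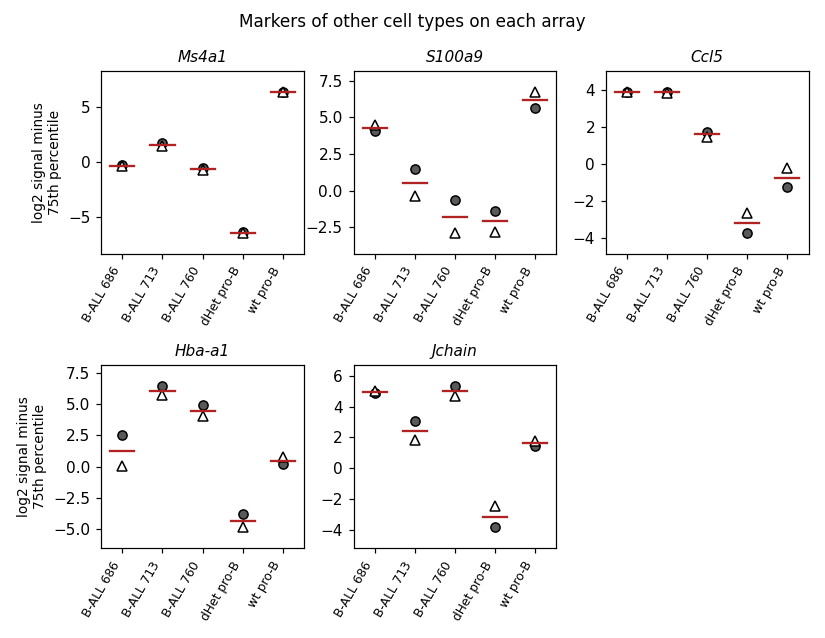
Level of 5 genes of other cells on each array (log2 signal relative to the array's 75th percentile), chosen after their values were seen, with replicate 1 as filled circles and replicate 2 as open triangles. Ms4a1 lies at 6.37 and 6.41 on the wt arrays and at -6.36 and -6.42 on the dHet pro-B arrays.

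The counts of this comparison changed with the signal used: the mean spot signal with normexp correction and an offset of 50 called 213 genes higher and 289 lower, and 11% of the genes called here were called in the same direction. Both groups lay on slide 3. In a fit with slide as a block 4593 genes were higher and 3317 lower, and in a fit of the 4 pro-B arrays alone 5032 and 3838. The spread of the main fit also pools the leukemia arrays. Replicate differences had an SD of 1.01, 0.77 and 0.76 in leukemias 686, 713 and 760, against 0.41 and 0.31 in dHet and wt pro-B cells. The median change of all genes was 0.13, and 0.48 with scaling by the array median, where 2681 were higher and 1467 lower, or -0.10 on probes detected on all arrays, where 1873 were higher and 2827 lower.

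The overlap of both comparisons with wt asked which differences of the leukemias were also present in non-leukemic dHet pro-B cells. Genes higher in both numbered 1480, against 754 for independent lists, and genes lower in both 1319, against 591. Cish, Socs2 and Ffar2 were among those higher and Ikzf1, Ms4a1 and Fcmr among those lower. These genes were 61.3% of those higher and 61.4% of those lower in dHet pro-B cells, and 32.8% and 33.2% of those of the leukemias. Both comparisons used the same 2 wt arrays, which can give overlap without a shared change. With wt replicate 1 for the leukemias and replicate 2 for dHet pro-B cells, 544 genes were higher and 515 lower in both, against 230 and 213 for independent lists. The other way round they were 627 and 492, against 251 and 197. These fits rest on lone wt arrays of the same slide and cell source, so a property of the wt cells or their slide is still shared. In opposite directions were 275 genes, Myc among them.

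The last comparisons set each leukemia against the other 2. Leukemia 713 differed most, with 1282 genes higher and 935 lower, and leukemia 686 least, with 252 and 365, while leukemia 760 had 773 and 958. The order of 713 and 760 was not stable, since leukemia 760 had more changed genes on slide 1 alone and without either array of leukemia 713. Leukemia 713 had 5.14-fold more Mycn, a relative of Myc (2.36 ± 0.20, n = 2 arrays against 4, adjusted p = 0.000684), and less Dntt, the terminal transferase that adds nucleotides during V(D)J joining (-2.54 ± 0.30, adjusted p = 0.00199). Leukemia 760 had 8.43-fold more Dntt (3.08 ± 0.30, adjusted p = 0.00115), more Kit (1.24 ± 0.16) and less Flt3 (-2.54 ± 0.51). Leukemia 686 had more Cdkn2a (adjusted p = 0.00455), detected on its replicate 2 only and on no array of the other 2, and less Mycn (-1.69 ± 0.20, adjusted p = 0.0075). Kit was also lower in leukemia 713 (-1.71 ± 0.16), Bcl2 higher there (1.13 ± 0.26) and Igll1 higher in leukemia 760 (0.67 ± 0.16).

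In leukemia 686 Psma8 (6.41 ± 1.08), Cibar1 (5.85 ± 1.20), the growth factor relative Fgf12 (5.56 ± 0.92), Lrig3 (5.52 ± 0.80) and the neutrophil protein gene S100a8 (5.16 ± 0.66) were higher, and the globin genes Hbb-bt (-4.29 ± 0.74) and Hba-a1 (-3.99 ± 0.68) lower. The neutrophil genes Ltf and Fpr2 were at least 7.71-fold and 8.05-fold higher. In leukemias 686, 713 and 760, S100a9 had mean levels of 4.25, 0.56 and -1.77 and Hba-a1 of 1.27, 6.07 and 4.46. Whether the neutrophil and globin transcripts came from leukemia cells or from other cells in the samples was not tested. In leukemia 713 the fatty acid receptor gene Cd36 (7.13 ± 1.37), Rtn1 (6.94 ± 0.95), the transcription factor gene Foxc1 (6.72 ± 1.16) and the lymphocyte adhesion gene Cd2 (6.0 ± 0.77) were higher. The growth factor receptor adaptor gene Grb10 (-5.06 ± 0.97) and Ddc (-5.30 ± 1.02) were lower, and Hs3st2 was at least 49.9-fold higher. In leukemia 760 Vill (5.52 ± 0.76) and Wdr86 (5.42 ± 0.53) were higher, and Xlr4b (-5.79 ± 0.76), the protease inhibitor gene Slpi (-4.94 ± 0.47) and Fcrla (-4.70 ± 0.72) lower. Rtn1 was at least 29.7-fold lower there. Several of these genes were detected on only part of the arrays of the lower side, and with the others at the lowest level well above background the changes were smaller. They were then 5.82 for Psma8, 4.88 for Cibar1, 4.13 for Fgf12 and 4.89 for Lrig3 in leukemia 686, 6.42 for Cd36 in leukemia 713 and -3.78 for Fcrla in leukemia 760.

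The p-values of these comparisons rest on the spread between arrays of 1 group, pooled over all 5 groups, and not on that between mice. Replicate differences had an SD of 0.41 and 0.31 across genes in dHet and wt pro-B cells. In leukemias 686, 713 and 760 it was 1.01, 0.77 and 0.76, so the pooled spread is small for the leukemias. Of the calls in leukemia 686, 0% held in the fit of the 6 leukemia arrays alone. Normexp called 0 genes in leukemia 686 by limma, against 404 higher and 363 lower at an unadjusted p under 0.05. It called 249 higher and 108 lower in leukemia 713 and 72 and 129 in leukemia 760, and the fit of the 6 leukemia arrays alone 551 and 359, and 259 and 426. With slide as a block leukemia 686 had 909 genes higher and 1267 lower, leukemia 713 had 2649 and 2254, and leukemia 760 had 1820 and 1930. On slide 1 alone the numbers were 1740 and 1342, 2220 and 1595, and 1561 and 2346 for the 3 leukemias, and on slide 2 alone 638 and 760, 2023 and 1861, and 1286 and 1465.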

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

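The tests of the brightest genes of a leukemia, of the 2 Ebf1 probes and of later B cell and myeloid transcripts were chosen only after the result was seen, and the tests of carried signal and of a higher background on slide 1 were written before it. Between the leukemias, 11 of the named genes reported here passed in opposite directions against wt pro-B cells in 2 leukemias, among 216 such genes in all. In leukemia 686 Ptpn14, a tyrosine phosphatase gene, was 5.06 higher on the log2 scale than in the other 2 (adjusted p = 0.00305), and Fpr2, a receptor of phagocytes, 4.74 higher (adjusted p = 0.0139). In leukemia 713 Prdm8 was 6.07 higher (adjusted p = 0.00146), the chemokine receptor gene Ackr2 5.38 higher (adjusted p = 0.00195), Cask 4.37 higher (adjusted p = 0.00258) and the aminopeptidase gene Enpep 4.12 higher (adjusted p = 0.00248), while Dok7 fell by 4.04 (adjusted p = 0.00334). In leukemia 760 Tdrkh was 6.22 higher (adjusted p = 0.000502), Vill 5.52 higher (adjusted p = 0.00422), Enpp4 4.23 higher (adjusted p = 0.000721) and the potassium channel gene Kcnk5 2.67 higher (adjusted p = 0.00265). These are fitted differences; Ptpn14, Fpr2, Prdm8, Cask, Tdrkh and Enpp4 were not above background in the other 2 leukemias, nor Dok7 in leukemia 713. As bounds they were at least 10.0-fold, 8.05-fold, 20.8-fold, 15.5-fold, 24.6-fold and 9.94-fold higher and 16.1-fold lower. Enpep and Kcnk5 were above background on 2 and Vill and Ackr2 on 3 of the 4 other arrays. In each comparison 2 arrays of 1 mouse were set against 4 arrays of the other 2 mice, and the adjusted p-values are from limma. A difference between the mice themselves was not tested and stays open.

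Signal of 1 leukemia's own genes on the slide 1 arrays of the other leukemias was weighed in 6 pairs of leukemias. It followed the owner's level with a median Spearman's rho of 0.326, which could be signal carried between samples; slide 2 is no fair comparison, since the genes were chosen as dim there. The owner's probes lay a median of 0.0801 above probes dim in all leukemias on the log2 scale, from -0.0826 to 1.36, highest for the 23 probes of leukemia 686, so a higher background is also possible. For the brightest of these genes the excess was 2.07, from the same 3 probes of leukemia 713 read in 2 pairs. It was 1.58 on slide 1 and 1.46 on slide 2 in leukemia 686, and 2.56 and -0.25 in leukemia 760. Too few probes were bright to tell the explanations apart, and both remain possible.

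The 2 Ebf1 probes differed in dHet pro-B cells. The second probe fell by 3.39 against wt, more than the loss of 1 of 2 copies can produce, and gene dose alone is unlikely. It read well above background on all 10 arrays, so a poor probe near the background is unlikely too. The 2 wt arrays differed by 0.187, but their differences over all genes had an SD of only 0.31, so this shows little. A probe that steadily reads another transcript was not excluded. Transcripts that start or end at different places were not tested, and the cause of the difference is unknown.

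Wt pro-B arrays held transcripts of later B cells and of myeloid cells. Of the later B cell genes 84.0%, and of the myeloid genes 77.3%, were well above background on both wt arrays and higher than on both dHet pro-B arrays, so RNA of other cells in the sorted fraction may have added to the differences. The myeloid list, which holds neutrophil genes such as Camp and S100a9, had a median change of -2.88 in dHet against wt pro-B cells. That difference is the one that prompted the test, so it cannot decide whether Ebf1 and Pax5 dose alone was the cause. The share was 34.5% of all tested genes. It was also 100% of the MHC class II and immediate early lists, 66.7% of the MYC list, 60% of the erythroid list and 57.1% of the genes activated by EBF1 and PAX5, so a high share is not particular to other cells. Sorting from bone marrow, culture and the Rag2 genotype differed together and stay untested.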

How the results depend on the processing

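The fits with a percentile over detected probes, with arrays of 1 slide only and with slide as a random block for the lists were chosen only after the result was seen. Counts below are genes higher and lower, and the cause was not tested where a count changed, unless it follows from how the fit was built.

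With the mean spot signal and normexp correction in place of the processed signal 2748 genes were higher and 2139 lower in the leukemias against wt, 1570 and 1566 against dHet pro-B, and 213 and 289 between the pro-B groups. Leukemia 686 had 0 and 0 by limma, against 404 and 363 at an unadjusted p under 0.05, leukemia 713 had 249 and 108, and leukemia 760 had 72 and 129. The share of calls kept in the same direction was 56.1%, 45.3% and 11% for the comparisons with pro-B cells, 16.0% for leukemia 713 and 10.7% for leukemia 760. With quantile normalization it was between 81.5% and 86.5%, and with the authors' value table between 76.5% and 82.8%, where leukemia 686 had 579 genes lower. Between 35.7% and 52.4% of probes per array were well above background, which limits the signal available to any correction. Whether this, the change of signal or the offset of 50 lost the calls was not tested.

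Scaling by the array median left 2280 genes lower against wt, 1976 lower against dHet pro-B, 127 higher in leukemia 686, 505 lower in leukemia 713 and 616 lower in leukemia 760. Within a comparison it moves all genes by a constant, and more calls were lost than gained except against wt. The percentile over detected probes gave 2959 higher against wt and 416 higher in leukemia 686. Without a filter on dim probes 27191 genes were tested, with 1117 and 1279 between the pro-B groups, 37 and 34 in leukemia 686, 574 and 397 in leukemia 713, and 308 and 493 in leukemia 760. With a filter on all 10 arrays 9557 genes were tested, so genes silent in 1 group were lost by construction. It left 1732 lower against wt, 2163 lower against dHet pro-B, 986 lower between the pro-B groups, 116 higher in leukemia 686, 824 higher in leukemia 713, and 493 and 449 in leukemia 760. A 2-fold minimum, which can only remove calls, left 2680 higher against wt, 1870 and 2129 against dHet pro-B, 1563 higher between the pro-B groups, 619 lower in leukemia 713 and an overlap of 814 genes higher. With separate wt arrays for the 2 comparisons, an alternative added after the result was seen, the overlap was 544 and 515, or 627 and 492 the other way round, as fits with lone wt arrays call fewer genes.

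With slide as a random block, at a consensus correlation of 0.66, 2978 and 2192 genes passed against wt and 1872 and 1437 against dHet pro-B. This fit also took arrays as replicates in place of mice. With slide as a fixed block 4593 and 3317 passed between the pro-B groups, 909 and 1267 in leukemia 686, 2649 and 2254 in leukemia 713, and 1820 and 1930 in leukemia 760. The block takes up the difference of slide 2 from slide 1, which passed upward in 1142 genes and downward in 2072 on average over the 3 mice. Pairing by replicate number gave 4961 and 4366 against wt, 3730 and 3946 against dHet pro-B, 2976 and 2537 between the pro-B groups, and 359 and 519, 1607 and 1152, and 940 and 1150 in leukemias 686, 713 and 760. For the leukemias against wt and dHet pro-B, this pairing also took arrays as replicates in place of mice. With the 4 pro-B arrays alone 5032 and 3838 passed. With the 6 leukemia arrays alone leukemia 686 had 0 and 0 by limma, against 724 and 838 at an unadjusted p under 0.05, leukemia 713 had 551 and 359, and leukemia 760 had 259 and 426. Slide 1 alone gave 1740 and 1342, 2220 and 1595, and 1561 and 2346 in the 3 leukemias, and slide 2 alone 638 and 760, 2023 and 1861, and 1286 and 1465.

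Leaving out 1 array at a time assumed that a lone array varies like the others. Against wt, 2955 to 4470 genes were higher, lowest without wt replicate 1, and 2448 to 3775 lower, with 2448 to 2629 without either wt array. Against dHet pro-B, 1543 to 3209 were higher and 1436 to 3252 lower, with at most 1570 and 1709 without either dHet pro-B array. Between the pro-B groups, 1078 to 2647 were higher and 1166 to 2488 lower, with at most 1228 and 1240 without any of the 4 pro-B arrays. For leukemia 686, 103 to 545 were higher, with 138 and 545 without its replicates 1 and 2 and 103 without a wt array. Lower there were 124 to 358, with 124 to 227 without a wt or dHet pro-B array, either array of 713 or replicate 1 of 760. For leukemia 713, 692 to 1322 were higher, with at most 722 without either of its arrays, and 445 to 1059 lower, lowest without its replicate 2. For leukemia 760, 339 to 839 were higher, with at most 514 without either of its arrays or a wt array, and 650 to 1324 lower. Leaving out 1 mouse gave 4209 to 4906 higher and 3719 to 4439 lower against wt, and 2768 to 3667 and 3146 to 4128 against dHet pro-B.

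No list passed camera with an estimated correlation, against 7 up and 3 down, 9 up and 4 down, and 4 up and 7 down in the 3 comparisons; at an unadjusted p under 0.05 there were 1 and 1, 0 and 1, and 2 and 3, and by fry 11 and 6, 9 and 6, and 11 and 7. Against wt 5 lists fell with normexp and 5 without a filter, and against dHet pro-B 7 fell with slide as a random block.

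Among named genes 5 values that passed in the main fit or in the alternative turned sign. Against dHet pro-B these were Lpl with normexp (-0.0534), Vpreb1 with quantile normalization (0.0705) and Socs2 with the mean of its probes (-0.22), where the second probe runs against the first. In leukemia 760 they were Cdkn2a with normexp (0.12) and Lin28b on slide 2 alone (1.43). Cdkn2a was undetected on all arrays of 713 and 760 and Lin28b on all 6 leukemia arrays, so these 2 turns of sign carry no meaning. Of all values of named genes under the alternatives 12440 were unchanged in call, 1039 lost the call and 122 gained one. Values that passed in neither fit count as unchanged even where their sign turned.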

Other observations

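The tests named below with a value from the 2 Ebf1 probes or from later B cell and myeloid transcripts were chosen only after the result was seen. The named genes took several courses across wt pro-B, dHet pro-B and leukemia. Ikzf1 fell in steps, with mean levels of 4.43, 2.27 and 1.16. Kit was highest in dHet pro-B cells, at 3.31 against -1.55 in wt and 0.40 in the leukemias, and Myc was lowest there, at 0.01 against 1.27 and 4.67. Cish and Socs2, the latter at its main probe, were higher than wt in dHet pro-B cells and in the leukemias. The second Socs2 probe did not pass in the leukemias against wt (0.34 ± 0.39). Shmt2 and the folate carrier gene Slc19a1 were higher in the leukemias than in either pro-B group. The dHet pro-B cells were obtained as c-Kit-positive cells and cultured with IL-7, while the wt cells were freshly sorted. Genotype, source and culture therefore cannot be told apart in these courses.

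Dntt and Mycn differed between the leukemias. Dntt had levels of 8.44 and 8.14 in leukemia 760 against 4.91 and 4.19 in leukemia 713, and Mycn had levels of 1.98 and 1.77 in leukemia 713 against -1.08 to -0.06 in the other 2. Cdkn2a was well above background on 3 arrays only, at -1.80 on replicate 2 of leukemia 686 and at -1.32 and -1.01 in dHet pro-B cells.

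A loss of the Ebf1 transcripts read by the second probe could precede leukemia, since this probe fell by 3.39 in dHet against wt pro-B cells. Sequencing of Ebf1 transcripts in freshly sorted pro-B cells of dHet and wt mice would tell a change of promoter use from an effect of the culture or of the targeted allele. Higher Myc and folate genes in the leukemias may be tied to each other or to lymph node growth in general, and lowering Myc in leukemia cells and measuring Shmt2 and Slc19a1 would separate these. The share of later B cell genes higher in the sorted wt cells, 84.0%, could come from admixed cells or from normal maturation that culture prevents. Single-cell sequencing of the sorted fraction would show whether Ms4a1 and S100a9 lie in the same cells as Rag1.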
